A study of Homo sapiens with 24 samples.

How the data were processed

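Small RNA was sequenced from SBC-3 cells, a human small cell lung cancer line, 72 h after reverse transfection with 10 nM of a small interfering RNA (siRNA) or antisense oligonucleotide (ASO). There were 24 libraries in 8 groups of 3. A control siRNA (siCtrl) was set beside 2 siRNAs against SFPQ (siSFPQ-2 and siSFPQ-3) and 2 against NONO (siNONO-3 and siNONO-4), and a control ASO (ASO-Ctrl) beside 2 ASOs against NEAT1 (ASO-NEAT1-1047 and ASO-NEAT1-1473). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, 100 ng of total RNA received spike-in oligonucleotides and went into a QIAseq library kit, which tags molecules with unique molecular identifiers.

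The deposited values are whole-number counts per mature miRNA locus and per spike-in, made with featureCounts 2.0.3 per the file headers. The submitters' processing notes name Trimmomatic 0.39, Bowtie 1.3.0, UMI-tools 1.1.1, Subread 2.0.3, DESeq2 1.38.1 and the genome build hg38, without order or parameters. Whether reads with one identifier were collapsed before counting is not given in the sources used here, so counting intervals cover counting error only. Each table held 2883 miRNA loci and 52 spike-ins. The loci belong to 2652 mature miRNAs, of which 169 have more than 1 locus. Of the 42 multi-locus miRNAs with over 2000 counts, 32 had loci within 5% of each other. For these, reads thus appear to have been counted at each locus to which they aligned. The locus with the largest total was therefore kept for each mature miRNA.

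Names were assigned by position, with a tolerance of 3 bases, from hairpins in GENCODE v29 (2574 miRNAs) or RefSeq GRCh38.p14 (74). The other 4 had no hairpin name. Coordinates are those of the tables, on hg38. Near-identical miRNAs also shared reads: 33 groups holding 82 miRNAs had counts within 10% of each other in every library at a mean count of at least 20. Among them are most let-7 members, miR-17-5p with miR-20b-5p, miR-18a-5p with miR-18b-5p, miR-19a-3p with miR-19b-3p, miR-99a-5p with miR-100-5p and miR-181a-1-3p with miR-181c-3p. Their values cannot be separated.

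Counts per mature miRNA were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). The filter filterByExpr with a minimum count of 10 kept 626 miRNAs, which held 99.97% of the counts. TMM factors set the library sizes, 1 model with a term per group was fitted to all 24 libraries (16 residual degrees of freedom, common biological coefficient of variation 0.250), and the quasi-likelihood test was applied. Unless another tool is named, every adjusted p below comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 626 miRNAs, at a threshold of 0.05. A standard error of a log2 fold change is the fold change divided by the square root of the test's F. CPM were computed on the TMM-scaled library size, and principal components used log2 CPM with a prior count of 2. A knockdown was the mean of its 2 reagents minus the matching control. Each reagent was also set against the control and against the other reagent. Differences between knockdowns and between the 2 controls were tested as contrasts of the same model.

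The design, the alternatives and the rule for named miRNAs were chosen before the data were examined. Named for each target were the 10 largest increases and 10 largest decreases that passed in the pooled and in both single-reagent comparisons at a mean of at least 10 CPM, the 5 most abundant miRNAs in the controls, and the tested members of the miR-17~92 cluster. Up to 4 members of each list that passed, 3 miRNAs in each direction for a difference, and miR-21-5p, miR-210-3p, miR-375-3p and miR-612 were also named. The 26 lists of families, genomic clusters and cell-type markers were written before any test was run, and 24 had at least 3 tested members. Products of both hairpin arms counted as members, so not every member of a family list carries the family's own sequence. Lists were tested with camera, with the correlation between members estimated from the data, and Benjamini-Hochberg adjustment over the 24. A list's count was also taken with p-values adjusted over the list alone.

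Where all 3 control libraries had 0 counts, a fold is a lower bound computed against a floor of 3 counts over the group. With 1 to 3 control counts, it is a ratio with its exact 95% binomial counting interval. Shared controls were weighed by simulating 50 sets of unchanged groups. The test was also run on simulated counts with 200 changed miRNAs per target. At a 1.5-fold change it recovered 22.4% of changed miRNAs for SFPQ, 28.4% for NONO and 28.4% for NEAT1. At a 2-fold change it recovered 67.2% of changed miRNAs for SFPQ, 64.2% for NONO and 67.2% for NEAT1. At 4-fold it recovered 89.4%, 93.9% and 97.0%.

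Alternatives were RLE size factors, library totals, no filter, a mean of at least 10 CPM, the replicate number as a block, only the compared groups, DESeq2 1.42.0, a fold of at least 1.5, a preset camera correlation of 0.01 and each library left out in turn. Added after the data were seen were all loci as deposited, shared reads collapsed, spike-in totals as library sizes, spike-in composition (the first principal component of the 49 spike-ins with a mean count over 50) as a covariate, and removal of 2 libraries with unusual spike-in composition. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Spike-ins stayed out of the library sizes and tests of the main model. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.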

Results

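The design asked how loss of SFPQ, an RNA-binding protein of the nucleus, changes miRNA levels, and how that compares with loss of its partner protein NONO and of NEAT1, the long noncoding RNA on which paraspeckles assemble. The libraries held between 2038382 and 4279644 counts each. The siCtrl libraries had 3153671, 3109715 and 2038382 counts in replicates 1 to 3, siSFPQ-2 had 3028928, 2433943 and 2449818, and siSFPQ-3 had 3255635, 3693324 and 2994281. Counts were 3673034, 2227390 and 3152562 for siNONO-3, and 3677533, 4279644 and 2489590 for siNONO-4. The ASO-Ctrl libraries had 4034465, 3628753 and 3919065, ASO-NEAT1-1047 had 3815942, 3889113 and 4010638, and ASO-NEAT1-1473 had 2461178, 2603194 and 3223547. Between 927 and 1220 miRNAs were detected per library, and the most abundant miRNA took 6.87% to 9.85% of the counts. All 24 pairs of replicates differed by more than sampling noise. Knockdown of the targets cannot be checked here, because their transcripts are not measured in small RNA tables. The miRNA inside NEAT1, miR-612 (chromosome 11, 65444473 to 65444497, exonic), had 1 count in 1 of the 24 libraries and was not tested.

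The 6 siSFPQ libraries separated from the other 18. The first principal component held 61.5% of the variance and ran from 18.1 to 28.1 in the siSFPQ libraries, against -9.91 to -5.89 in the rest. The second component held 9.94%, and on it siCtrl replicate 1 (11.7) and ASO-NEAT1-1047 replicate 3 (10.2) lay apart from the other libraries of their groups.

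**Figure D1:**
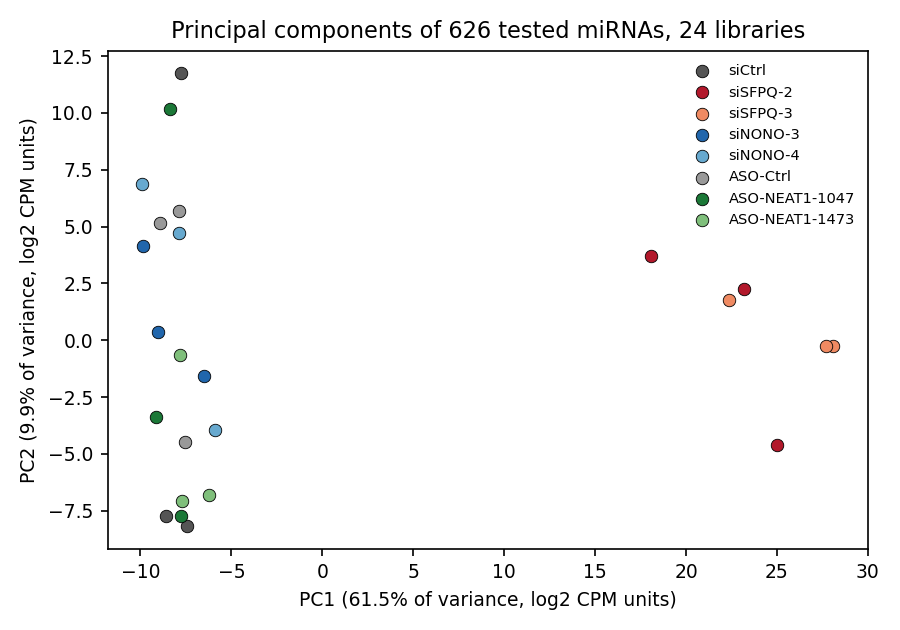
Principal components of log2 CPM of the 626 tested miRNAs, with 1 point per library coloured by group, the first component (61.5% of variance) on the x axis and the second (9.94%) on the y axis. The siSFPQ libraries lie between 18.1 and 28.1 on the first component and all other libraries between -9.91 and -5.89.

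The siSFPQ libraries were set against siCtrl to ask which miRNAs change when SFPQ is lost. The miR-302/miR-367 cluster, characteristic of embryonic stem cells, went from at most 1 count per tested member over the 3 siCtrl libraries to as much as 1093 CPM of miR-302c-3p in 1 siSFPQ-3 library. The miR-200 family, which keeps cells epithelial by restraining ZEB1 and ZEB2, rose in 6 of 7 tested members, products of both arms included. miR-21-3p, the passenger strand of the oncogenic miR-21, rose with a log2 fold change (log2FC) of 3.25 ± 0.22 (SE, 6 libraries against 3). The tumour-suppressive let-7 family was lower in 12 of 13 members, or 11 on library totals, though most of these members share reads. Of the 12 products of the MYC-induced oncogenic miR-17~92 cluster, 8 were lower, but only 4 on spike-in totals and 1 on library totals. The neural miR-9-5p, the most abundant miRNA in siCtrl, fell by 0.65 ± 0.12, from 90610 ± 7567 CPM (SD, n = 3) to 63770 ± 9525 with siSFPQ-2 and 52410 ± 5530 with siSFPQ-3. Its fall did not pass on library totals.

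Of the 626 tested miRNAs, 160 were higher and 142 lower, and 334 had an unadjusted p under 0.05. At least a 2-fold change was seen in 117 of the higher and 65 of the lower miRNAs. Higher miRNAs were the less abundant ones, with a median of 14.4 CPM and a median log2FC of 1.40, and lower ones had a median of 127 CPM and a median log2FC of -0.90. Among the 81 miRNAs at 1000 CPM or more, 4 were higher and 42 lower. DESeq2 gave 155 higher and 142 lower. Scaling moved this balance: with library totals 252 were higher and 67 lower, with a median log2FC over all tested miRNAs of 0.47 against 0.02 with TMM, and with spike-in totals 66.9% of the changed miRNAs were higher and 90 lower, with a median of 0.21.

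**Figure D2:**
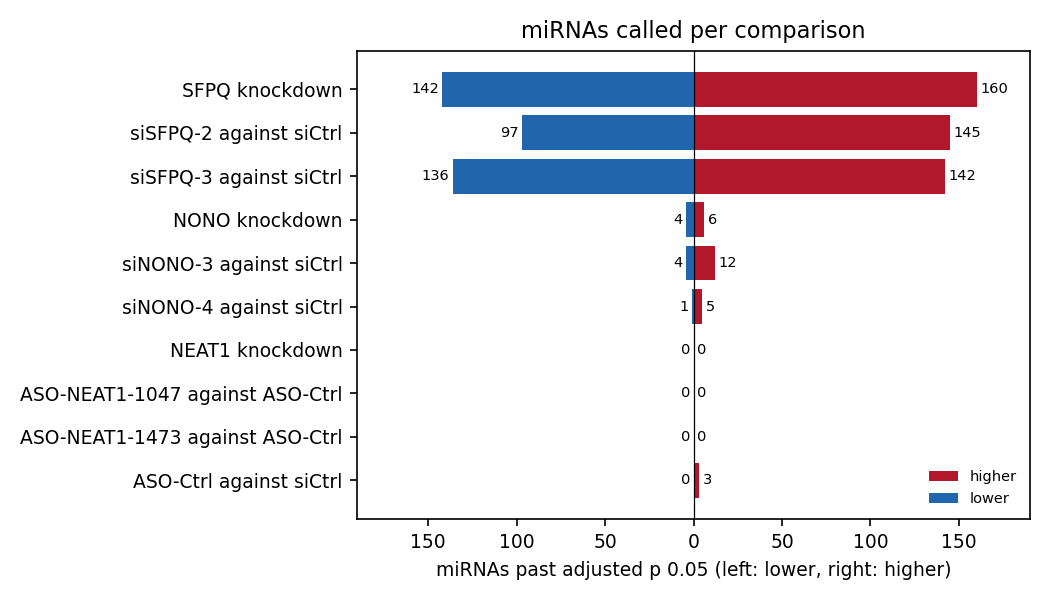
Number of miRNAs past an adjusted p of 0.05 in each comparison (x axis, bars to the left for lower and to the right for higher miRNAs, 626 tested in each). The SFPQ knockdown has 160 higher and 142 lower, the NONO knockdown 6 and 4, and the NEAT1 knockdown 0 and 0.

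The miR-302/miR-367 cluster lies on chromosome 4 (112647877 to 112648547, minus strand) within AC106864.1, where miR-302a, miR-302c and miR-302d are intronic and miR-302b-3p exonic. With 0 counts in siCtrl, miR-302d-3p was at least 441-fold higher over the pooled siSFPQ libraries (243 with siSFPQ-2 and 582 with siSFPQ-3) and miR-302a-3p at least 390-fold higher (212 and 518). With 1 siCtrl count each, the ratio was 4120 (95% counting interval 739 to 163000) for miR-302c-3p, 4040 (726 to 160000) for miR-302a-5p and 3690 (662 to 146000) for miR-302b-3p. The miR-302c-3p level was 505.8, 300.5 and 47.95 CPM in siSFPQ-2 replicates 1 to 3 and 1093, 839.3 and 179.6 CPM in siSFPQ-3, against a mean of 0.111 CPM in siCtrl. Replicate 3 was thus lowest in both groups. All 8 tested members of the miR-302/miR-367 and miR-371/miR-373 list rose, 8 when adjusted over the list alone, and all 8 also rose on library totals and on spike-in totals. Their median log2FC was 8.70 with members at 0 in siCtrl set to their bound.

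Outside that cluster, the highest increases among miRNAs named by rule, at a mean of at least 10 CPM, were each above every siCtrl library in 6 of 6 siSFPQ libraries, which chance gives in either direction for 2.38% of unchanged miRNAs not picked by their values. Named miRNAs were picked by the comparison with these same siCtrl libraries, so for them the separation is no further test. miR-141-5p of the miR-200 family (chromosome 12, 6964113 to 6964134, MIR200CHG intron) rose from 1.84 ± 0.173 CPM to 28.7 ± 13.7 and 40.3 ± 5.49 with the 2 siRNAs (log2FC 4.16 ± 0.39, adjusted p = 7.16e-09). miR-181a-1-3p (chromosome 1, 198859069 to 198859090) rose from 2.79 ± 1.51 CPM to 42.3 ± 13.1 and 33.97 ± 4.26 (3.74 ± 0.37, adjusted p = 1.91e-08), and miR-181c-3p, which shares its reads, by 3.66 ± 0.38. The KLF7 intronic miR-2355-5p (chromosome 2, 207110043 to 207110063) rose from 2.88 ± 0.5004 CPM to 39.3 ± 12.1 and 30.3 ± 3.56 (3.59 ± 0.28, adjusted p = 1.24e-09). miR-21-3p, exonic in VMP1 (chromosome 17, 59841311 to 59841331), rose from 99.1 ± 17.5 CPM to 973 ± 180 and 912 ± 134 (adjusted p = 1.15e-10). The guide strand miR-21-5p rose less, by 0.91 ± 0.25, from 32300 ± 10470 CPM to 57390 ± 10390 and 63910 ± 11730 (adjusted p = 0.00485). The islet and neuroendocrine miR-375-3p rose from 0.669 ± 0.409 CPM to 4.92 ± 0.643 and 6.33 ± 2.35 (2.99 ± 0.63, adjusted p = 0.000516).

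The 10 named decreases were below every siCtrl library in 6 of 6 siSFPQ libraries. miR-12135, in an intron of NEO1 (chromosome 15, 73299962 to 73299979), went from 1892 ± 202 CPM to 228 ± 94.9 and 240 ± 35.3 (log2FC -3.02 ± 0.19, adjusted p = 5.96e-11). The TATDN1 intronic miR-6844 (chromosome 8, 124508515 to 124508535) had a log2FC of -2.80 ± 0.33 (adjusted p = 2.60e-07), and the intergenic miR-4454 (chromosome 4, 163093607 to 163093626) one of -2.59 ± 0.21 (adjusted p = 1.26e-09). miR-421, in an intron of FTX (chromosome X, 74218392 to 74218414), dropped from 240 ± 20.3 CPM to 74.8 ± 9.35 and 59.0 ± 0.999 (-1.85 ± 0.16, adjusted p = 1.85e-09). The other named decreases were miR-301b-5p (-2.38 ± 0.32), miR-1269a (-2.19 ± 0.29), miR-1269b (-2.18 ± 0.30), the TP63 intronic miR-944 (-2.08 ± 0.30), the SKA2 intronic miR-301a-5p (-1.98 ± 0.22) and the CALCR intronic miR-653-3p (-1.75 ± 0.29), with adjusted p from 8.53e-08 to 2.76e-05. The MEST intronic pair miR-335-3p (-1.41 ± 0.14, adjusted p = 1.43e-08) and miR-335-5p (-0.86 ± 0.19, adjusted p = 0.000737) was among the 5 most abundant in siCtrl and fell. So did miR-9-5p (chromosome 5, 88666902 to 88666924, LINC00461, adjusted p = 0.000169, below every siCtrl library in 6 of 6), although its log2FC of -0.21 on library totals did not pass. The hypoxia-induced miR-210-3p fell by 0.77 ± 0.31 (adjusted p = 0.0460, lower in 2 of 6) and passed on neither library totals nor spike-in totals, nor without siCtrl replicate 2 or 3, but did so with -1.09 without siCtrl replicate 1.

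Most members of the miR-200, miR-192/miR-194/miR-215 and miR-181 lists were higher. In the miR-200 family, miR-141-3p (2.93 ± 0.25, adjusted p = 2.34e-09), miR-200a-3p (2.75 ± 0.23, adjusted p = 1.63e-09), miR-200c-3p (2.57 ± 0.33) and miR-200b-3p (2.13 ± 0.32) rose in 6 of 6 libraries, and miR-429 did not pass (-0.74, adjusted p = 0.328). All 6 members of miR-192/miR-194/miR-215, miRNAs of gut, liver and kidney epithelium, rose, with a median of 1.62. Examples are miR-192-5p (1.28 ± 0.21, adjusted p = 2.60e-05), miR-192-3p (1.75 ± 0.23, adjusted p = 1.62e-06) and miR-215-5p (1.75 ± 0.26, adjusted p = 9.75e-06). The lymphocyte-associated miR-181 family had 6 of 8 members higher (median 1.36), or 8 of 8 on library totals and on spike-in totals, which left 6 higher in each of the other two lists. The miR-181 list leaves out miR-181b-1-3p, which also rose (1.61, adjusted p = 0.00372). These counts were 6, 6 and 6 when adjusted over the list alone. As sets, with an estimated correlation, the miR-200 family had an adjusted p = 0.146, miR-192/miR-194/miR-215 an adjusted p = 0.316 and the miR-181 family an adjusted p = 0.335.

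The let-7 and miR-17~92 lists lay on the lower side. let-7a-3p (-1.38 ± 0.19, adjusted p = 3.74e-06), let-7i-5p (-0.95 ± 0.18, adjusted p = 0.000189) and let-7a-5p (-0.88 ± 0.21, adjusted p = 0.00136) were each below every siCtrl library in 6 of 6 libraries, and let-7e-3p did not pass (0.15, adjusted p = 0.810). The let-7 median was -0.89, or -0.44 on library totals and -0.69 on spike-in totals. In MIR17HG (chromosome 13, 91350618 to 91351382), miR-18a-5p had a log2FC of -1.23 ± 0.20 (adjusted p = 1.95e-05, 6 of 6 libraries), miR-17-3p of -0.68 ± 0.19 (adjusted p = 0.00562, 6 of 6), miR-17-5p of -0.81 ± 0.23 (adjusted p = 0.00638, 4 of 6), miR-20a-5p of -0.69 ± 0.16 (adjusted p = 0.000891, 4 of 6) and miR-20a-3p of -0.86 ± 0.19 (adjusted p = 0.000737, 4 of 6). miR-19a-3p (-0.77 ± 0.26, adjusted p = 0.0160) and miR-19b-3p (-0.77 ± 0.25, adjusted p = 0.0153) were below the lowest siCtrl library in 0 of 6, and miR-19b-1-5p (-0.54 ± 0.19, adjusted p = 0.0207) in 2 of 6. In siCtrl, miR-19b-3p was at 15330 CPM in replicate 1 and at 50990 and 59420 in the others, with 19330 to 32160 in the siSFPQ libraries. Without siCtrl replicate 1 its log2FC was -1.15 and passed. Leaving out siCtrl replicate 2 or 3 ended the calls of these 3 among the 8 lower members, with miR-19b-3p at -0.61 (adjusted p = 0.102) and -0.43 (adjusted p = 0.211). Not past the threshold were miR-92a-3p (-0.33, adjusted p = 0.393), miR-92a-1-5p (0.10, adjusted p = 0.774), miR-18a-3p (-0.37, adjusted p = 0.354) and miR-19a-5p (-0.70, adjusted p = 0.163). The cluster's median was -0.69, or -0.27 on library totals and -0.55 on spike-in totals. Adjusted over the list alone, 12 let-7 and 8 miR-17~92 members were lower. Most let-7 members share reads, as do miR-19a-3p and miR-19b-3p, so their counts are not of separate cases. The counts kept for miR-19b-3p are those of its locus on chromosome X. The let-7 and miR-17~92 sets had adjusted p = 0.316 and 0.335 with an estimated correlation.

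**Figure D3:**
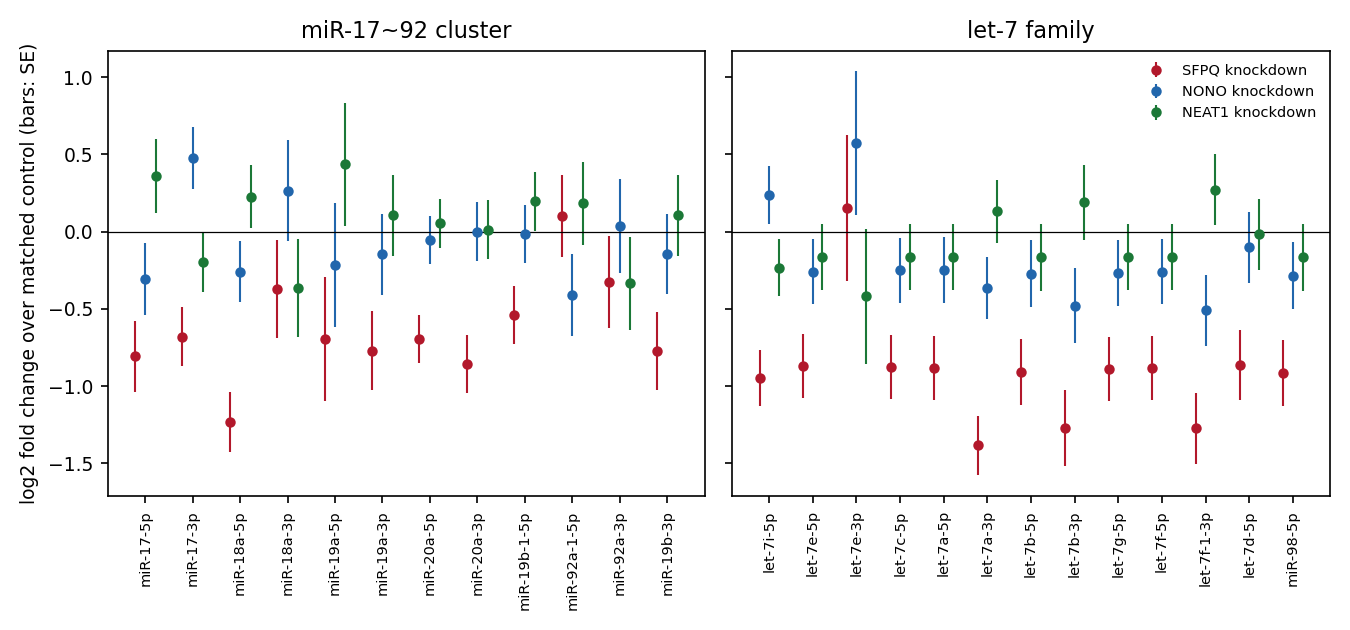
log2 fold change over the matched control (y axis, points with standard error bars) of the tested members of the miR-17~92 cluster and the let-7 family (x axis) after knockdown of SFPQ, NONO and NEAT1, on TMM scaling. For SFPQ, 8 of 12 cluster members and 12 of 13 let-7 members were lower, against 4 and 12 on spike-in totals and 1 and 11 on library totals. Most let-7 members share reads, as do miR-19a-3p and miR-19b-3p.

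Other lower lists after SFPQ knockdown also shrank on other scales. The miR-130/miR-301/miR-454 family had 7 of 10 lower (miR-454-5p -1.45 ± 0.20) and 1 higher, against 4 lower and 3 higher on library totals. The cell-cycle restraining miR-15/miR-16 family had 7 of 13 lower (miR-497-5p -1.33 ± 0.18, miR-16-5p -0.53 ± 0.15) and 1 higher, against 3 and 1 on library totals. The muscle list had 4 of 5 lower (miR-1-3p -1.19 ± 0.23) and 2 on library totals. The mesenchymal, endothelial and liver list had 6 of 9 lower (miR-143-3p -0.70, miR-126-3p -0.45), with a median of -0.43 that turned to 0.02 on library totals, where 0 were lower. The miR-106a/miR-363 cluster had 3 of 5 lower, against 1 lower and 1 higher on library totals. Adjusted over the list alone, these 5 lists had 7, 7, 4, 6 and 3 lower members, with miR-19b-2-5p (0.91) of the miR-106a/miR-363 cluster higher, and their sets had adjusted p from 0.316 to 0.491 with an estimated correlation. The p53-induced miR-34 family had 1 of 5 lower (miR-34a-5p -0.38 ± 0.14, adjusted p = 0.0284) and 0 on library totals or when adjusted over the list alone, with a median of -0.28 that turned to 0.15 on library totals. Mirtrons and capped precursors had 2 of 5 lower (miR-877-5p -0.88, miR-1226-3p -0.70) and 0 on library totals, where the median of -0.38 turned to 0.08. The miR-29 family had 2 of 7 lower (miR-29a-5p -0.85 ± 0.24, miR-29b-3p -0.46 ± 0.17), but 5 higher and 0 lower on library totals, and its median of 0.04 and mean of -0.13 differed in sign. The mirtron and miR-29 counts were also 2 and 2 lower when adjusted over the list alone.

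In 5 further lists some members were higher and none lower. The miR-424/miR-503/miR-450 cluster had 5 of 10 higher (miR-424-3p 2.16 ± 0.37), the miR-30 family 4 of 11 (miR-30c-2-3p 0.77 ± 0.26) and 8 when adjusted over the list alone, and the miR-23/miR-27/miR-24 clusters 3 of 8 (miR-27a-5p 2.09 ± 0.43, miR-23a-3p 0.67 ± 0.17). The inflammation-responsive list had 4 of 9 higher, among them miR-147b-3p (1.81) and the CREB-responsive miR-212-3p (1.33), and the miR-183/miR-96/miR-182 cluster 1 of 6 (miR-96-3p 1.65). None was lower on library totals or spike-in totals either. Lists with both directions were the neuronal and neuroendocrine miRNAs, with 2 of 14 higher (miR-138-5p 1.72 ± 0.36) and 5 lower (miR-218-5p -1.62 ± 0.17, miR-7-5p -0.69 ± 0.12), but 6 higher and 1 lower on library totals, miR-99/miR-100/miR-125 with 1 higher (miR-125a-3p 0.83) and 2 lower of 9 (miR-99a-5p and miR-100-5p, which share reads, -1.29 ± 0.30), and the miR-106b/miR-25 cluster with 1 higher (miR-25-5p 0.97) and 1 lower (miR-106b-5p -0.60) of 6, but 2 and 0 on library totals. miR-221/miR-222 had 1 of 4 lower (miR-222-5p -0.60), but 2 higher and 0 lower on library totals, and the 14q32 cluster had 0 of 7 past the threshold by edgeR over all miRNAs or over the list alone (median 0.36). Both tested blood cell miRNAs missed the threshold (miR-142-5p 0.04, miR-142-3p -0.52), as did the 1 tested C19MC member, miR-516a-5p (-0.80, adjusted p = 0.119). Adjusted over the list alone, these counts were the same except in the miR-30 family. The median and mean were above 0 while camera ranked the set downward for the neuronal list (0.18 and 0.23) and for miR-221/miR-222 (0.03 and 0.02). No set passed for SFPQ with an estimated correlation, the lowest adjusted p being 0.146, and 7 did with the preset correlation, namely miR-302/miR-367 with miR-371/miR-373, miR-200, miR-192/miR-194/miR-215, miR-181, let-7, miR-17~92 and miR-130/miR-301/miR-454.

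The 2 siRNAs against SFPQ acted alike in most of these miRNAs. With siSFPQ-2, 145 were higher and 97 lower (292 at an unadjusted p under 0.05), and with siSFPQ-3, 142 and 136 (316). Both siRNAs changed 216 in one direction, 127 higher and 89 lower, against 32.9 and 21.1 for independent lists. Unchanged groups simulated with a shared, simulated siCtrl group gave 0. None changed in opposite directions. Models of only the compared groups gave 105 with both siRNAs, 116 with siSFPQ-2 and 180 with siSFPQ-3. All 160 higher and 142 lower miRNAs of the pooled comparison had the same sign with each siRNA. Tested directly against each other, the siRNAs differed in 4 miRNAs, all lower with siSFPQ-3 (40 at an unadjusted p under 0.05, DESeq2 4). miR-22-3p, exonic with miR-22-5p in MIR22HG, was at 603 ± 40.9 CPM with siSFPQ-2 and 346 ± 31.0 with siSFPQ-3, against 372.5 ± 28.5 in siCtrl (difference -0.80 ± 0.16, adjusted p = 0.0112). miR-22-5p (chromosome 17, 1713952 to 1713973) was at 77.1 ± 5.29 and 37.5 ± 7.86 CPM, against 34.5 ± 7.51 in siCtrl (-1.04 ± 0.23, adjusted p = 0.0263). The other two, miR-548b-3p and miR-1322, were below 10 CPM on average and were chosen after their values were seen. miR-548b-3p had a mean of 11.7 CPM with siSFPQ-2 and 4.11 with siSFPQ-3 (-1.52 ± 0.28, adjusted p = 0.00917), and miR-1322 had 9 counts with siSFPQ-2, 0 with siSFPQ-3 and 34 in siCtrl (adjusted p = 0.0153). The count of 4 fell to 0 without siSFPQ-2 replicate 1 or siSFPQ-3 replicate 1, and to 1 without siSFPQ-3 replicate 3.

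The siNONO libraries were set against siCtrl to ask whether loss of the partner protein changes the same miRNAs. Loss of NONO raised the miR-34 family, miRNAs induced by p53 that restrain the cell cycle, in 4 of 5 tested members. miR-34c-5p (chromosome 11, the intergenic miR-34b/c hairpins lie at 111512950 to 111513473) rose from 12.4 ± 2.69 CPM in siCtrl to 148 ± 33.3 with siNONO-3 and 77.0 ± 10.1 with siNONO-4 (log2FC 3.10 ± 0.29, adjusted p = 9.56e-08). miR-34b-5p rose from 5.42 ± 1.46 CPM to 61.0 ± 8.30 and 30.5 ± 0.371 (2.96 ± 0.29, adjusted p = 1.52e-07), and miR-34a-5p, exonic in MIR34AHG (chromosome 1, 9151735 to 9151756), from 3244 ± 537 CPM to 9040 ± 1067 and 5843 ± 498 (1.16 ± 0.15, adjusted p = 1.43e-05). miR-34a-3p rose by 1.15 ± 0.24 (adjusted p = 0.00860), and miR-34b-3p had 2.10 ± 0.59 (adjusted p = 0.0742). For each of these 5, all 6 siNONO libraries lay above every siCtrl library. The increase was smaller against ASO-Ctrl, with 1.49 for miR-34c-5p, and ASO-Ctrl itself exceeded siCtrl by 1.61 for miR-34c-5p and 1.46 for miR-34b-5p.

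**Figure D4:**
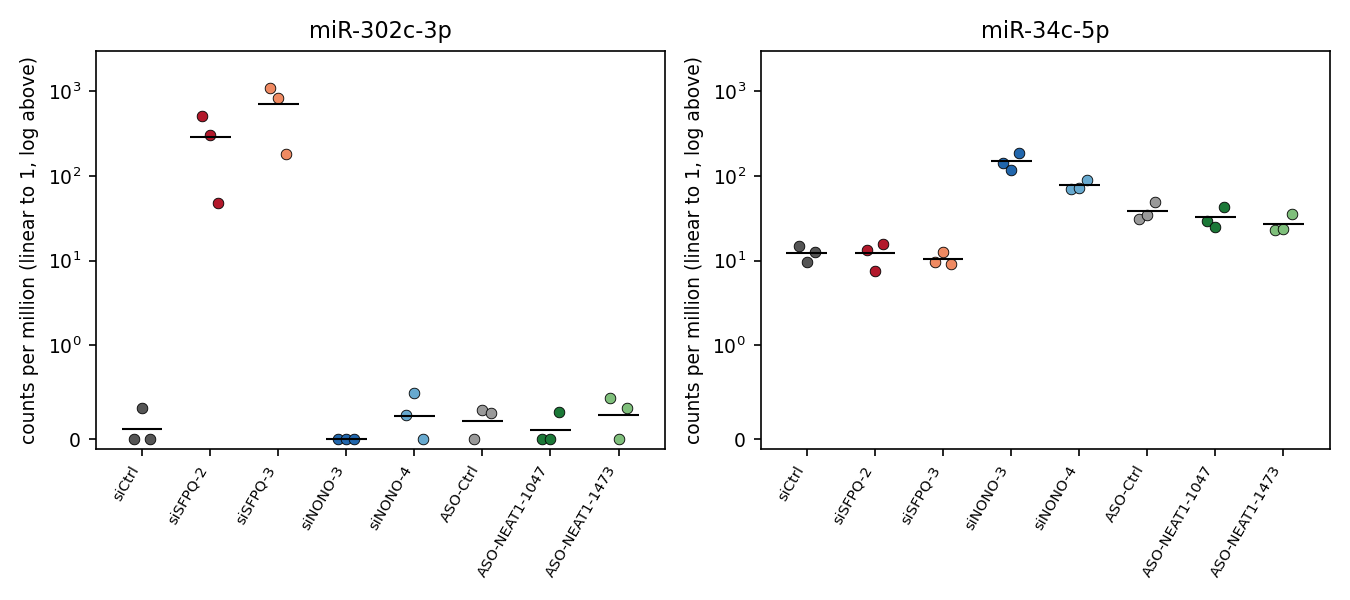
CPM (y axis, linear up to 1 and log above) of miR-302c-3p and miR-34c-5p in the 8 groups (x axis), with 1 point per library and a line at each group mean. miR-302c-3p lies between 47.95 and 1093 CPM in the siSFPQ libraries against a mean of 0.111 in siCtrl, and miR-34c-5p has means of 148 and 77.0 CPM with the siNONO siRNAs against 12.4 in siCtrl.

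After NONO knockdown 10 of the 626 miRNAs changed, 6 higher and 4 lower, with 74 at an unadjusted p under 0.05 and 13 higher and 7 lower by DESeq2. With spike-in composition as a covariate, an alternative chosen after seeing the data, 42 were higher and 13 lower. Beyond the miR-34 family these are outside the naming rule, except the miR-1269 pair and miR-676-3p, and were chosen after their values were seen. miR-675-3p, made from H19, rose by 1.28 ± 0.31 (adjusted p = 0.0297), and the CALCR intronic miR-489-3p by 0.71 ± 0.18 (adjusted p = 0.0457). Lower were miR-1269a (-1.47 ± 0.29, adjusted p = 0.00648), miR-1269b (-1.42 ± 0.30, adjusted p = 0.00860), the EDA intronic miR-676-3p (-1.09 ± 0.23, adjusted p = 0.00970) and miR-181b-1-3p (-2.38 ± 0.61, adjusted p = 0.0457), which had 19 counts in siCtrl and 2 and 9 with the siRNAs. All 6 siNONO libraries lay beyond every siCtrl library for each. Against siCtrl, siNONO-3 changed 12 higher and 4 lower and siNONO-4 changed 5 higher and 1 lower, with 3 miRNAs changed by both. In the main edgeR model the siRNAs did not differ in any miRNA (0 past the threshold, 38 at an unadjusted p under 0.05, 7 by DESeq2). Some alternative edgeR fits, such as that with the spike-in covariate, did call differences between them. Library totals gave 17 higher and 4 lower, with a median log2FC over all miRNAs of 0.12, and spike-in totals 3 and 3. A fit of only the compared groups called 3 higher and 0 lower. Without siCtrl replicate 1, 10 were higher and 1 lower, and 4 of the 10 calls stayed, namely miR-34a-5p, miR-34b-5p, miR-34c-5p and miR-489-3p. The other 6 kept their sign at adjusted p from 0.0533 to 0.0825, with log2FC of 1.02 for miR-34a-3p, 0.96 for miR-675-3p, -2.56 for miR-181b-1-3p, -0.91 for miR-676-3p, -0.96 for miR-1269a and -0.90 for miR-1269b. Without siCtrl replicate 1 and ASO-NEAT1-1047 replicate 3, whose spike-in composition lay farthest from the rest, 33 were higher and 14 lower, and 8 of the 10 calls stayed. Without siCtrl replicate 3 there were 3 higher, and without siNONO-4 replicate 1 there were 12.

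The miR-34 family passed its set test (median 2.10, adjusted p = 7.24e-07 with an estimated correlation), and all 5 members were higher when adjusted over the list alone. Every other list had 0 members past the threshold by edgeR over all miRNAs in the model with group terms alone, and the miR-181 list leaves out the lower miR-181b-1-3p. Other models called members of these lists. With the spike-in covariate, miR-126-3p, miR-143-3p, miR-141-3p and miR-497-5p were among the higher ones, and miR-450b-5p, miR-450a-1-3p, miR-542-3p and miR-181b-2-3p among the lower ones. Adjusted over the list alone, 2 were higher in miR-200, 1 in the neuronal list, 2 in the blood cell list and 4 in the mesenchymal, endothelial and liver list, and 2 were lower in miR-181 and 3 in miR-424/miR-503/miR-450. The next set had an adjusted p = 0.591, and the preset correlation added miR-200 (0.0426) and miR-424/miR-503/miR-450 (0.00277). Abundant miRNAs that fell after SFPQ knockdown had small values here that did not pass, with a log2FC of -0.24 ± 0.19 for miR-335-5p, -0.25 ± 0.14 for miR-335-3p and -0.15 ± 0.26 for miR-19b-3p. Median, mean and test differed in sign for miR-30, miR-106a/miR-363, miR-192/miR-194/miR-215, miR-99/miR-100/miR-125, miR-302/miR-367 with miR-371/miR-373, neuronal and inflammation-responsive miRNAs, with medians between -0.07 and 0.05.

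The ASO-NEAT1 libraries were set against ASO-Ctrl to ask whether the paraspeckle RNA itself matters for miRNA levels. No miRNA passed the threshold after NEAT1 knockdown by edgeR (0 higher and 0 lower, 19 at an unadjusted p under 0.05 where 31 are expected by chance, 0 by DESeq2), and the lowest adjusted p was 0.908. The miRNAs most abundant in the cells had log2FC of 0.12 ± 0.13 for miR-9-5p, 0.05 ± 0.19 for miR-335-5p, 0.17 ± 0.14 for miR-335-3p and 0.10 ± 0.26 for miR-19b-3p, with adjusted p from 0.908 to 0.943. miR-21-5p had 0.24 and miR-375-3p 0.95 ± 0.72. Over the 211 miRNAs above 100 CPM the median half-width of the 95% interval of the log2FC was 0.417. In simulation a 1.5-fold change after NEAT1 knockdown was recovered for 28.4% of changed miRNAs, and for 50% of those above 100 CPM. In the main edgeR model ASO-NEAT1-1047 and ASO-NEAT1-1473 each gave 0 miRNAs (5 and 42 at an unadjusted p under 0.05, 0 and 0 by DESeq2), and 0 differed between them (15, 0). Fits without a filter or of only the compared groups called 1 miRNA in some of these comparisons.

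All lists had 0 members past the threshold by edgeR after NEAT1 knockdown, and the lowest adjusted p of a set was 0.842 with an estimated correlation. Adjusted over the list alone, 1 inflammation-responsive member was lower, miR-212-3p (-1.12 ± 0.36, adjusted p = 0.908 over all miRNAs). With the preset correlation miR-99/miR-100/miR-125 passed (adjusted p = 0.00783, median -0.31), with miR-99b-5p at -0.51 ± 0.27 and miR-125a-5p at -0.49 ± 0.21. Median, mean and test differed in sign for miR-15/miR-16 (0.03, -0.02, down), miR-192/miR-194/miR-215 (-0.07, 0.12, down), 14q32 (-0.14, -0.07, up), the mesenchymal list (-0.02, 0.13, up) and miR-302/miR-367 with miR-371/miR-373 (0.00, 0.21, down).

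Differences between knockdowns were tested directly. SFPQ and NONO knockdown differed in 354 miRNAs, 186 higher and 168 lower after SFPQ knockdown (379 at an unadjusted p under 0.05). The largest positive differences were miR-302c-3p, miR-302d-3p and miR-302b-3p, and the largest negative ones miR-34b-5p (-3.35 ± 0.22, adjusted p = 1.11e-11), miR-34c-5p (-3.24 ± 0.21, adjusted p = 1.15e-11) and miR-12135 (-2.97 ± 0.18, adjusted p = 3.29e-12). SFPQ and NEAT1 knockdown differed in 147 miRNAs, 76 higher and 71 lower (243), led by miR-302a-5p, miR-141-5p (4.62 ± 0.55) and miR-181a-1-3p (3.95 ± 0.49) on one side and miR-12135 (-3.36 ± 0.29), miR-6844 (-3.12 ± 0.47) and miR-301b-5p (-2.46 ± 0.45) on the other. NONO and NEAT1 knockdown differed in 7 miRNAs, 6 higher and 1 lower (75), led by miR-34c-5p (3.45 ± 0.36), miR-34b-5p (3.01 ± 0.37) and miR-34a-5p (1.29 ± 0.20), with miR-676-3p (-1.47 ± 0.33, adjusted p = 0.0297) the 1 lower. This last count was 29 without siCtrl replicate 1, 15 without ASO-NEAT1-1047 replicate 3 and 3 or 4 without any 1 of 11 other libraries.

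Across the 626 miRNAs, which are not independent replicates, the SFPQ and NONO effects had a Pearson r of 0.163 and a Spearman rho of 0.22. Unchanged groups simulated with a shared siCtrl group gave an r of 0.705 and a covariance of 0.134 ± 0.0201 (SD), beside an observed covariance of 0.143. The siCtrl counts were drawn too, and all libraries independently. Deviations of the measured siCtrl libraries, such as that of replicate 1, are thus left out of the simulation. Of the miRNAs changed in both, 0 were higher in both and 3 lower in both, against 1.53 and 0.907 for independent lists and 0 in simulation. The 3 were miR-676-3p and the miR-1269 pair, whose members had nearly equal mean levels (20.58 and 20.53 CPM) and are hardly separate cases. Without siCtrl replicate 1, a library of both comparisons, the 3 lost their NONO calls (edgeR adjusted p from 0.0533 to 0.0825). miR-489-3p fell after SFPQ (-1.02) and rose after NONO knockdown, and miR-181b-1-3p rose after SFPQ knockdown (1.61) and fell after NONO knockdown. miR-34a-5p also fell after SFPQ (-0.38) and rose after NONO knockdown, but its fall did not pass on library totals. Only 3 of 6 siSFPQ libraries lay below every siCtrl library, and siSFPQ-2 (2870 to 3200 CPM) lay within the siCtrl range (2690 to 3760 CPM). SFPQ and NEAT1 effects, which share no library, had an r of 0.0635 and a rho of 0.0487. The r turned to -0.288 with the spike-in covariate and to -0.0717 without siCtrl replicate 1 and ASO-NEAT1-1047 replicate 3. In the model without the covariate and with all libraries these effects had a covariance of 0.0397 beside -0.00267 in simulation. Over the 609 miRNAs above the floor these were an r of 0.00126 and a covariance of 0.000485. The 2 siRNAs of SFPQ had an r of 0.970 and a covariance of 2.81 (simulated 0.133), or 0.933 and 1.19 over those 609, those of NONO 0.604 and 0.202 (0.135), and the ASOs of NEAT1 0.469 and 0.0836 (0.108). Controls of 3 libraries cannot be split into parts of 2, so part of any excess may come from the shared controls.

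The controls were compared to measure the background between the oligonucleotide types. ASO-Ctrl exceeded siCtrl in 3 miRNAs, with 0 lower (44 at an unadjusted p under 0.05, 5 by DESeq2). miR-34c-5p was higher by 1.61 ± 0.30 (adjusted p = 0.0103) and miR-34b-5p by 1.46 ± 0.31 (adjusted p = 0.0229), so 2 members of the miR-34 family also differed between the controls. Set against ASO-Ctrl in place of siCtrl, the siNONO libraries still had 4 of 5 members higher, among them miR-34c-5p with a log2FC of 1.49, miR-34a-5p with 0.84 and miR-34a-3p with 1.12. The other, miR-9901, had 52 counts in ASO-Ctrl and 2 in siCtrl (adjusted p = 0.0165) and was chosen after its values were seen. The count of 3 fell to 0 without siCtrl replicate 2 or ASO-Ctrl replicate 3 and to 1 without ASO-Ctrl replicate 1, and rose to 8 without siCtrl replicate 1.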

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

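The tests of spike-in composition and of the removal of siCtrl replicate 1 in this part were chosen only after the results were seen. The direct comparison of the 2 siRNAs against SFPQ was planned, and it differed in 4 miRNAs. The difference of siSFPQ-3 from siSFPQ-2 was -1.04 in log2 for miR-22-5p, -0.80 for miR-22-3p, -1.52 for miR-548b-3p and -4.72 as fitted for miR-1322, which had 9 counts against 0. In siCtrl both miR-22 strands were near their siSFPQ-3 level, at 34.5 CPM against 37.5 for miR-22-5p and 372.5 against 346 for miR-22-3p.

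The spike-in oligonucleotides, outside the comparisons of the report, took a higher percent of all counts in some treated libraries than in any control library, where the highest value was 1.89%. They took 3.29% in siSFPQ-2 replicate 2, 2.50% in siSFPQ-2 replicate 3, 1.99% in siSFPQ-3 replicate 1 and 2.05% in siSFPQ-3 replicate 3. In the NONO groups they took 1.96% in siNONO-3 replicate 1, 2.06% in siNONO-3 replicate 2, 1.98% in siNONO-4 replicate 1 and 2.16% in siNONO-4 replicate 2. These percents were not tested, and a group of 3 libraries by itself gives little ground to judge a single library far from the rest.

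The spread between replicates was shared between spike-ins and miRNAs, and the number of NONO calls moved with it. The main component of the spike-ins and the main within-group component of the miRNAs had a Pearson r of 0.983 and a Spearman rho of 0.968 over the 24 libraries (permutation p = 1e-05 each, the smallest that the permutations can give, 1 relation tested), and r was 0.971 without siCtrl replicate 1 and ASO-NEAT1-1047 replicate 3, the 2 farthest. Spike-ins are added to purified RNA, so differences in library preparation are a candidate explanation for this component, which held 33% of the within-group variance of the miRNAs. Without siCtrl replicate 1 alone 4 of the 10 NONO calls were kept, and without both of these libraries 8 of the 10 were. ASO-NEAT1-1047 replicate 3 is no part of this comparison, and the fit without both called more miRNAs as a whole (33 higher and 14 lower). The 8 kept calls therefore do not decide whether siCtrl replicate 1 was the origin of most of the 10. Without it alone all 10 kept their sign. Some shrank, such as miR-1269a from -1.47 to -0.96, and others grew, such as miR-34c-5p from 3.10 to 3.29. Loss of NONO itself stays open as a biological explanation for the calls.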

How the results depend on the processing

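The alternatives chosen after seeing the data were all loci as deposited, shared reads collapsed, spike-in totals, the spike-in covariate and removal of siCtrl replicate 1 and ASO-NEAT1-1047 replicate 3. Over all alternatives and libraries left out, 58 of 2248 values of the miRNAs named by rule changed sign, and 0 of these passed the threshold before or after. Over the alternatives 1216 of their values stayed on the same side of the threshold, 43 no longer passed and 11 passed newly, and with 1 library left out these numbers were 943, 33 and 2. Counts depended more on the processing, and the cause was not tested except where it is given. Depth limits the least abundant miRNAs: in simulation a 2-fold change after NEAT1 knockdown was recovered for 67.2% of all changed miRNAs and for 94.1% of those above 100 CPM.

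With library totals, higher and lower SFPQ calls were 252 and 67 in place of 160 and 142 (227 of these shared; the median over all miRNAs was 0.47 in place of 0.02), NONO higher calls 17 and siNONO-4 calls 10, because TMM factors shift the centre. With spike-in totals the SFPQ knockdown had 90 lower, the SFPQ siRNAs differed in 1, the NONO knockdown had 3 higher, siNONO-3 10 and siNONO-4 2 calls, and NONO and NEAT1 differed in 2. With RLE factors NONO and NEAT1 differed in 4 and the controls in 5. A minimum of 10 CPM, which tests fewer miRNAs, gave 94 higher for SFPQ, 0 between its siRNAs, 3 between the siRNAs against NONO, 3 for siNONO-4, 229 for SFPQ against NONO, 4 for NONO against NEAT1 and 1 set for SFPQ (miR-200). Without a filter, NONO had 11 higher and 8 lower, 5 with both siRNAs, the ASOs against NEAT1 differed in 1, ASO-NEAT1-1047 had 1, and 4 sets passed for SFPQ (let-7, miR-192/miR-194/miR-215, miR-200 and the mesenchymal list).

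DESeq2 gave 13 higher and 7 lower for NONO, 5 with both siRNAs, 7 between them, 11 for siNONO-4, 12 for NONO against NEAT1 and 5 between the controls. Fits of only the compared groups have fewer libraries to estimate the spread and gave 116 for siSFPQ-2, 180 for siSFPQ-3, 105 with both, 0 between them, 3 higher and 0 lower for NONO, 3 for siNONO-3, 2 for siNONO-4, 1 for ASO-NEAT1-1473 and 0 between the controls. The spike-in covariate gave 24 between the siRNAs against SFPQ, 42 higher and 13 lower for NONO, 20 with both siRNAs, 12 between them, 52 for siNONO-3, 37 for siNONO-4, 239 for SFPQ against NEAT1, 38 for NONO against NEAT1, 7 between the controls and an r of -0.288 between SFPQ and NEAT1 effects. Removal of the 2 libraries gave 33 higher and 14 lower for NONO, 16 with both siRNAs, 10 between them, 31 for siNONO-3, 41 for siNONO-4, 242 for SFPQ against NEAT1, 92 for NONO against NEAT1, 28 between the controls, 1 set for SFPQ (miR-130/miR-301/miR-454) and an r of -0.0717. The controls differed in 6 with all loci and in 5 with shared reads collapsed. With the preset correlation 7 sets passed for SFPQ, 3 for NONO and 1 for NEAT1.

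Replicate numbers are not said to mark a shared day. In 6 of 28 group pairs every same-numbered pair of libraries correlated above 0.1, and 52 of the 84 same-numbered pairs did so singly. In every group pair without siCtrl, replicates 1 correlated positively and so did replicates 3, while replicates 2 went in both directions. The mean correlation was 0.164 for pairs with the same number and -0.0821 for others. The second mean is tied to the first, because values were centred within groups of 3. Something shared by same-numbered libraries is thus not excluded. With the number as a block, the SFPQ siRNAs differed in 12, NONO had 12 higher and 12 lower, 5 with both siRNAs and 1 between them, siNONO-3 had 26, NONO and NEAT1 differed in 13 and the controls in 5. List members called for NONO with the block, beside the miR-34 family, were miR-17-3p (higher), miR-450b-5p, miR-542-3p and miR-181b-2-3p (lower). The block moved no other count by more than 1.5 times.

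With 1 library left out, SFPQ had 138 to 165 higher and 113 to 137 lower, siSFPQ-2 had 191 to 232, siSFPQ-3 227 to 257 and both 169 to 202. The SFPQ siRNAs differed in 0 (without siSFPQ-2 replicate 1 or siSFPQ-3 replicate 1) to 6 (without siSFPQ-2 replicate 3), and in 1 without siSFPQ-3 replicate 3. NONO had 3 higher (without siCtrl replicate 3) to 12 (without siNONO-4 replicate 1), 10 without siCtrl replicate 1, and 1 lower (without siCtrl replicate 1) to 4. siNONO-3 had 6 (without its replicate 3) to 15, with 8 without siCtrl replicate 3 and 10 without siNONO-3 replicate 2. siNONO-4 had 2 (without its replicate 3) to 11 (without siCtrl replicate 1), with 3 without siCtrl replicate 3 or siNONO-4 replicate 1, and 2 (without siNONO-4 replicate 3) to 5 (without siCtrl replicate 2) changed with both. The siRNAs against NONO differed in 0 throughout, and all NEAT1 counts were 0 throughout. SFPQ against NONO gave 328 to 366 and SFPQ against NEAT1 121 to 202. NONO against NEAT1 gave 29 without siCtrl replicate 1 and 15 without ASO-NEAT1-1047 replicate 3, 3 without siCtrl replicate 3, siNONO-3 replicates 1 or 3, siNONO-4 replicate 3, ASO-Ctrl replicate 2, ASO-NEAT1-1047 replicate 2 or ASO-NEAT1-1473 replicate 3, and 4 without siNONO-4 replicate 2, ASO-Ctrl replicate 3 or ASO-NEAT1-1473 replicates 1 or 2. The controls differed in 0 (without siCtrl replicate 2 or ASO-Ctrl replicate 3) to 8 (without siCtrl replicate 1), and in 1 without ASO-Ctrl replicate 1. Sets passing numbered 0 for SFPQ, 1 for NONO and 0 for NEAT1 throughout. The correlation with SFPQ effects ran from 0.0836 to 0.333 for NONO and from -0.00498 to 0.103 for NEAT1. Leaving out siCtrl replicate 2 or 3 ended the SFPQ calls of miR-19a-3p, miR-19b-3p, miR-19b-1-5p and miR-210-3p.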

Other observations

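The splits of the libraries and the test of host gene length were chosen before their results were seen, and the tests of hairpin arms, miR-548, miR-302/miR-367 and miR-34 only after. Neighbouring hairpins were compared after SFPQ knockdown. Hairpins less than 10000 bases apart on one strand formed 15 clusters with at least 3 changed miRNAs, and in 15 of 15 all changed members went in one direction, a count without a chance value. Members that did not pass also ran the other way, such as miR-19b-2-5p (0.907) and miR-130b-3p (0.177). Several of these share reads, so they are not separate cases: with each group of shared reads counted once, 13 clusters had at least 3 changed miRNAs, and 13 went in one direction. On library totals 2 of the 12 with at least 2 changed miRNAs held both directions, and on spike-in totals 1 of 14. Apart from clusters described above, an intron of CLCN5 (chromosome X, 50003167 to 50014670) holds miR-532, miR-188, miR-500a, miR-362, miR-501, miR-660 and miR-502, with 8 of 13 tested products lower and a median log2FC of -0.62. In CALCR (chromosome 7, 93482784 to 93483968) 3 of 3 products of miR-653 and miR-489 were lower, with a median of -1.75, while their median after NONO knockdown was 0.643. In FTX, miR-545 and miR-374a (chromosome X, 74287126 to 74287346) had 3 of 4 lower with a median of -0.925. The cell-cycle restraining miR-195 and miR-497 (chromosome 17, 7017628 to 7017999) had 4 of 4 lower with a median of -1.17. Upward, MIR181A1HG (chromosome 1, 198858887 to 198859130) had 3 of 3 higher with a median of 1.61, and MIR200CHG (chromosome 12, 6963703 to 6964176) 4 of 4 with a median of 3.55. These are values on TMM scaling, on which all tested miRNAs had a median of 0.02, against 0.47 on library totals.

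The primate-specific miR-548 family, a large family of related hairpins in many introns, had 26 of 68 tested members higher and 2 lower after SFPQ knockdown, with a median log2FC of 0.348. With members that share reads collapsed, 22 of 56 were higher and 3 lower. Only members with counts within 10% of each other in every library were collapsed. Reads shared in part can still be counted in several members, so a role of shared reads stays open. Over all 626 miRNAs, 160 were higher and 142 lower. As a set, chosen after its values were seen, it had p = 0.502 by camera with an estimated correlation. Among the 95 hairpins whose more abundant arm changed, the 2 arms had one sign in 83, in 67 of 74 without miRNAs that share reads, and in 59 of 66 when also limited to 1 hairpin per genomic cluster. Neighbouring hairpins are not independent. The less abundant arm moved further in 40 of 95, but choosing hairpins by the more abundant arm tilts this count against the less abundant one, so it leaves open which arm moves further. Because SFPQ is known to act on the transcription of long genes, miRNAs of long host genes were tested for lower values. Over 278 host genes, which are not independent replicates, length and log2FC had a Spearman rho of 0.0909 (permutation p = 0.132, 95% interval -0.0323 to 0.215) and a Pearson r of 0.0268, and the median was 0.00314 over the longest 25% of hosts and -0.185 over the shortest 25%, so a fall with length was not seen.

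All miRNAs named miR-302 or miR-367, untested ones and miR-302e outside the chromosome 4 cluster included, held 43435 counts in the 6 siSFPQ libraries, and the cluster alone 42823. Scaling was tested first, and all 9 tested miRNAs of these names, 8 of them in the cluster, stayed higher and past the threshold on spike-in totals. Pluripotent cells in the siSFPQ cultures were looked for by the miR-371/miR-373 cluster, which such cells can also express and which had 0 counts there. This cluster alone cannot exclude cells that express miR-302/miR-367 without it. Reads from another library of the series would need a source, and the other 18 libraries together held 175 counts of these names and 38 of the cluster. Release of the cluster from repression after loss of SFPQ may account for the rise, a hypothesis formed on these same data and not tested further.

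The miR-34 increase after NONO knockdown was weighed against low values in siCtrl, since miR-34b-5p and miR-34c-5p were also higher in ASO-Ctrl. siCtrl was not alone in its low level. Mean miR-34c-5p was 12.4 CPM in siCtrl, 12.2 in siSFPQ-2 and 10.4 in siSFPQ-3. It was 38.0 CPM in ASO-Ctrl, 32.7 in ASO-NEAT1-1047 and 27.4 in ASO-NEAT1-1473. For miR-34b-5p the same groups had 5.41, 4.95 and 3.54 CPM against 15.2, 14.8 and 14.4. Against ASO-Ctrl, 4 of 5 members were higher and past the threshold, with a median log2FC of 1.28 in place of 2.10. On spike-in totals 3 of the 4 called members passed, and miR-34a-3p did not (adjusted p = 0.0809). A p53 response to loss of NONO may account for the increase, and it stays open. Among miRNAs of the fixed lists that p53 is also known to induce, miR-192/miR-194/miR-215 had 0 of 6 members past the threshold and a median of -0.00502, with members in both directions, which decides nothing.

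Other splits of the same libraries were fitted with 1 term per new group. For the SFPQ knockdown, 1 of 84 splits gave as many higher miRNAs (145, highest other 0) and 1 of 84 as many lower ones (102, highest other 0). With both siRNAs 1 of 100 gave as many (135, highest other 0). No other split gave any call, so a random regrouping of these libraries does not give such counts. The shares are the smallest that the splits can give and are not adjusted for the number of such tests. A difference between cultures that the libraries of a group share cannot be seen by regrouping them. For NONO, 3 of 84 gave as many higher (3, highest other 22, with siCtrl replicates 2 and 3 and siNONO-4 replicate 1 against the rest) and 3 of 100 as many with both siRNAs (2, highest other 2). These shares are under 0.05 but not adjusted for the number of such tests, and 2 other splits gave more higher miRNAs. Chance is therefore not excluded for these counts. The lower count was 0 in this fit (highest other 12), so 84 of 84 gave as many by construction, and chance is neither excluded nor shown for the 4 lower miRNAs of the full model. For NEAT1, 84 of 84 splits gave as many higher (0, highest other 111) and as many lower (0, highest other 128), and 100 of 100 as many with both ASOs (0, highest other 122), again by construction. The split with the highest counts set ASO-Ctrl replicates 2 and 3 and ASO-NEAT1-1047 replicate 3 apart from the rest, which points to a structure among these libraries other than their groups, as do the NONO splits with 22 higher and 12 lower. These splits followed spike-in composition. The libraries set apart for NEAT1 had the lowest values of the spike-in component in that comparison (-1.71, -1.39 and -3.16). Those of the NONO split with 22 higher had the highest (1.97, 1.69 and 1.81). Those of the NONO split with 12 lower had the lowest (-5.21, -1.15 and -1.16). Passing sets numbered 0 in the real split and at most 0, 0 and 1 in the others for SFPQ, NONO and NEAT1 (84 of 84 splits as many each). These fits of 2 groups, which lose the miR-34 set, therefore exclude nothing. SFPQ against NONO (1 of 100, 368, highest other 137) was matched by no other split drawn. This share is also the smallest that 100 can give and is not adjusted. For SFPQ against NEAT1 (2 of 100, 143, highest other 160) and NONO against NEAT1 (2 of 100, 7, highest other 8), 1 other split each gave a higher count. Chance is not excluded for these differences.

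Comparisons of 3 libraries with 3 have 10 splits, so the share is never under 0.1. Real and highest other counts were 116 and 0 for siSFPQ-2, 180 and 0 for siSFPQ-3, 3 and 1 for siNONO-3, 2 and 54 for siNONO-4, 0 and 192 for ASO-NEAT1-1047, 1 and 77 for ASO-NEAT1-1473 and 0 and 92 for ASO-Ctrl against siCtrl. The splits with 54, 192, 77 and 92 calls also point to a structure of the samples. Between the reagents they were 0 and 19 for SFPQ, 0 and 0 for NONO and 0 and 2 for NEAT1. As many calls as in the real split came in 1 split for siSFPQ-2, siSFPQ-3 and siNONO-3, in 2 for siNONO-4 and ASO-NEAT1-1473, and in 10 for the others.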
